A study of Mus musculus with 9 samples.

How the data were processed

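Messenger RNA of mouse sciatic nerve was measured on Illumina bead arrays, with total RNA extracted by Trizol and labelled with biotin, per the labels. The 9 samples fell into newborn, P10 and P60 groups of 3 by their titles, and 0 columns of per-sample values were left unmapped. The deposited signal table holds a linear intensity for each of 45281 probes per array, background-subtracted and not normalized between arrays. Between 29.9% and 32.9% of these intensities lay below 0, and their 75th percentile ranged from 89.3 to 155. Per the file headers, each intensity has a detection p-value, whose values fall in 936 steps. The authors also deposited a log2 table of 20362 probes, each detected on 1 or more arrays. The columns of that table have a median of 7.43, share the rank order of their array's signal (Spearman's rho 1), and match log2 of the shifted and quantile-normalized signal for 100% of values within 0.01, which settles scale and direction. GenomeStudio and lumi are named in the submitters' processing notes, and their versions and settings are not given in the sources used here.

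Intensities were processed with neqc in limma 3.58.1 (R 4.3.3), which applies a normexp background correction based on the detection p-values, an offset of 16, quantile normalization and log2. Probes with a detection p under 0.01 on 3 or more of the 9 arrays were kept, 18659 in all. The platform annotation gave 1 gene symbol to 17276 probes of the authors' table and several to 12, and did not list 3074. Of the first, 17260 matched a gene ID of the reference table (GRCm38.p6), with 0 symbols changed, and 16 kept the annotation's symbol. Detected probes without 1 symbol, 2725 in number, were tested only in an alternative. For each gene the probe with the highest mean was used, which left 10319 genes. Of 3896 genes with more than 1 detected probe, 126 had probes called in opposite directions for P10 against newborn, 107 for P60 against P10 and 183 for P60 against newborn. The files mark no saturated probe. In newborn, Cdkn1c had a signal of 85.1% to 99.5% and Igf2 of 68% to 88.2% of that of the array's brightest probe, and folds of such bright probes may be understated. Where a gene was detected on no array of its dimmer stage, the fold is a lower bound. It sets the brighter stage's mean against the mean, over the dimmer stage's arrays, of the higher of the lowest detected signal and the gene's own.

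A mean per stage was fitted over all 9 arrays with lmFit and eBayes (6 residual and 3.75 prior degrees of freedom, median moderated SD 0.148 on the log2 scale). P-values were two-sided and adjusted by Benjamini-Hochberg over genes within each comparison, with a threshold of 0.05. The titles number the replicates of each stage 1 to 3, and the labels do not say that a number marks a shared litter, batch or day. Deviations of same-numbered P10 and P60 arrays from their stage means correlated across genes at 0.152, 0.136 and 0.308, each over 0.1. P10 replicate 1 correlated as well with P60 replicate 2 (0.159), and P10 replicate 2 with P60 replicate 1 at 0.11. The deviations of a stage's arrays cancel out, and those of P60 replicates 1 and 2 opposed those of P60 replicate 3 (-0.821 and -0.864). The same-numbered correlations are therefore not separate agreements, and the data do not settle whether the number pairs these stages. With newborn arrays the same-numbered correlations were 0.0859, -0.0142 and -0.0112 for P10 and 0.28, -0.373 and -0.22 for P60, which gives no pairing. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1. Each of 35 gene lists was tested against all other genes with camera, with a preset correlation of 0.01, and adjusted over 105 tests. With an estimated correlation, the calls of cholesterol synthesis and cell cycle held for P10 against newborn, the calls of cholesterol synthesis and imprinted growth genes held for P60 against P10, the calls of cell cycle and imprinted growth genes held for P60 against newborn, and no other list call held.

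The lists covered myelin proteins, cholesterol synthesis, fatty acids, sphingolipids and galactolipids, cell cycle, immature and repair Schwann cell genes, Schwann cell transcription factors, the methionine cycle, DNA methylation, fibrillar collagen and matrix, basal lamina, imprinted growth genes, neurotrophic factors, oxidative phosphorylation, antigen presentation, interferon-stimulated genes, circadian clock, immediate early genes and ribosomal proteins. Other lists held markers of endothelial cells, pericytes and smooth muscle, fibroblasts, perineurial cells, macrophages, mast cells, lymphocytes, neutrophils, erythroid cells, adipocytes, skeletal muscle, neurons, cartilage and bone, melanocytes and keratinocytes, and sex-linked genes. Few listed genes were measured for neurons (4 of 17), erythroid cells (3 of 14), and cartilage and bone (3 of 12). The same held for adipocytes (6 of 16), lymphocytes (2 of 16), neutrophils (2 of 10), melanocytes (2 of 8) and keratinocytes (1 of 12). Named genes were, per comparison, the 8 largest rises and 8 largest falls past the threshold whose arrays did not overlap, leaving out clone and predicted names, and up to 4 members of each list with the largest change. They also took in the 6 largest peaks and troughs at P10, and Mbp, Pmp22, Egr2, Ngfr, Mki67, Dnmt1, Dnmt3a, Dnmt3b, Gnmt and Mat2a whatever their result. Other genes fixed by name in that rule are not reported here.

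The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were no background correction, scaling to the 75th percentile, the authors' log2 table, other detection filters, all probes tested separately, only the 6 arrays of the compared stages, the replicate number as a block, array weights, a minimum log2 fold change of 1, leaving out each array, and camera with an estimated correlation or fry in its place. The ranges of adjusted p over all alternatives leave out fry, which does not compare a list with other genes, and the minimum fold change, which leaves p as it is. Lists were not tested with other detection filters, all probes separately, array weights or the unblocked fits of only the 6 arrays compared. The ranges of lists leave these settings out, and those of named genes leave out all probes tested separately. Normexp with no scaling between arrays, the block over the P10 and P60 arrays alone, and list counts without P60 replicate 3, were chosen after seeing the data. The fit was tested on simulated data with 200 changed genes among 10319. For P10 against newborn it recovered 56.7% of changes of 0.5 on the log2 scale and 97% of changes of 1, with 19 false calls. For P60 against P10 it recovered 38.8% and 94%, with 4 false calls, and for P60 against newborn 46.3% and 97%, with 7. The simulation gave all stages the same spread per gene, as the fit assumes, while the P60 arrays varied more. It therefore does not show recovery or false calls under the uneven spread of the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.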

Results

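Sciatic nerves of C57Bl6J mice, an inbred laboratory strain, were profiled at 3 stages of postnatal life: newborn, postnatal day 10 (P10) and postnatal day 60 (P60). The sciatic nerve carries the axons of sensory and motor neurons, and much of its RNA comes from the cells around them, among them the Schwann cells that wrap axons in myelin during the first weeks after birth. The series title places the work in a study of DNA methylation in myelinating Schwann cells, so the comparisons ask how messenger RNA in the nerve changed between these stages. Each stage had 3 samples, 9 arrays in all, and every sample was RNA from pooled nerves of mice of either sex. The labels do not say whether the replicates of a stage came from separate animals or dissections, so the p-values measure only the spread between these samples, which may be technical.

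Each array read 45281 probes. Detected probes, with a detection p-value under 0.01, numbered 17603 to 18105 on the newborn arrays, 16362 to 17076 at P10 and 16172 to 17105 at P60. The number of arrays, 3 per stage, limits the precision. Values are normalized log2 intensities of 1 probe per gene with their SD (n = 3), or log2 fold changes ± SE, with adjusted p-values from limma over 10319 genes. A fold written as at least N-fold is a lower bound, given where no array of the dimmer stage detected the gene.

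The 9 arrays were separated by stage. Of 10319 genes, 7678 (74.4%) differed between stages at an adjusted p under 0.05. From newborn to P10, 3070 genes rose and 3132 fell, and from P10 to P60, 2042 rose and 1913 fell. With no scaling between arrays these counts were 1298 rises and 5695 falls, then 2476 and 1135. Changes of 2-fold or more were 946 rises and 967 falls in the first step, and 381 and 415 in the second. The arrays of the compared stages did not overlap for 74.4% of genes in the first step and 50.5% in the second, where chance gives 10%. P60 replicate 3 stood apart from the other P60 arrays: Pearson's r across genes, which are not independent replicates, was 0.98 and 0.978, against 0.996 between those arrays. Without P60 replicate 3, 7366 genes changed from newborn to P10 and 4891 from P10 to P60. The fit shares 1 spread over the stages, though the P60 arrays varied more. In fits of only the 6 arrays compared, 7338 and 3316 genes changed in the 2 steps, against 6202 and 3955.

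**Figure D1:**
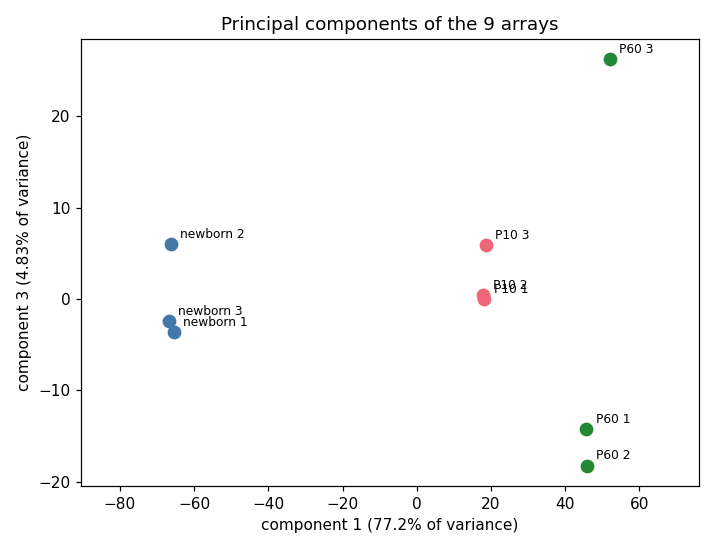
Principal components 1 and 3 of the 9 arrays over 10319 genes, in units of log2 intensity, with each dot an array coloured by stage. Component 1 (77.2% of variance) orders newborn, P10 and P60, and on component 3 (4.83%) P60 replicate 3 lies at 26.2, away from the other P60 arrays at -14.2 and -18.2.

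Between birth and P10, genes of myelin and of lipid synthesis rose and genes of cell division fell. Of 18 measured myelin protein genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone). The myelin list had a median log2 fold change of 1.34 and a list test adjusted p = 3.82e-05 (adjusted p = 0.082 with an estimated correlation). Drp2, which codes for a dystrophin-related protein of the Schwann cell membrane, rose 22.8-fold (log2 fold change 4.51 ± 0.15). Nfasc, an adhesion protein of the node of Ranvier, rose 11.7-fold, Ncmap 6.78-fold and Gldn 4.1-fold. Pmp22, a major peripheral myelin protein, rose 1.71-fold (log2 fold change 0.77 ± 0.11). Probes of Mbp, myelin basic protein, differed. The brightest, at 14.78 ± 0.13 in newborn and 15.02 ± 0.059 at P10, had a log2 fold change of 0.24 ± 0.10 (adjusted p = 0.058). Its signal was 65.1% to 86.3% of that of the brightest probe on the same array, over all 9 arrays, so its fold may be understated. The 4 dimmer probes had 2.57, 2.23, 1.82 and 0.29. The bright probe passed the threshold without newborn replicate 3 (adjusted p = 0.0261) and without P60 replicate 3 (adjusted p = 0.0205), with a range of 0.00376 to 0.526 over all alternatives. It also passed with 75th percentile scaling (adjusted p = 0.00376), array weights (adjusted p = 0.021) and only the 6 arrays compared (adjusted p = 0.0296). With no scaling between arrays it had -0.099 (adjusted p = 0.526).

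Cholesterol is a main lipid of myelin, and genes of its synthesis rose. Of 18 measured cholesterol synthesis genes, 18 rose and 0 fell (18 and 0 adjusted over the list alone). Cholesterol synthesis had a median log2 fold change of 1.73 and a list test adjusted p = 4.64e-08 (adjusted p = 0.0361 with an estimated correlation). Sc5d rose 6.42-fold, Hsd17b7 4.55-fold, Mvd 4.45-fold and Lss, lanosterol synthase, 4.31-fold (log2 fold change 2.11 ± 0.13). A dimmer probe of Lss had a log2 fold change of 0.32. Of 15 measured fatty acid genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone). Fatty acid synthesis and elongation had a median log2 fold change of 0.86 and a list test adjusted p = 0.000424 (adjusted p = 0.061 with an estimated correlation). Acss2 rose 4.93-fold and the elongase Elovl6 3.19-fold. Of 14 measured sphingolipid and galactolipid genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone). Sphingolipid and galactolipid synthesis had a median log2 fold change of 0.57 and a list test adjusted p = 0.000621 (adjusted p = 0.149 with an estimated correlation). Ugt8a, which makes the myelin lipid galactosylceramide, rose 4.63-fold, and Sptlc2, a subunit of the first enzyme of sphingolipid synthesis, 5.16-fold.

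Genes of cell division fell. Of 33 measured cell cycle genes, 0 rose and 33 fell (0 and 33 adjusted over the list alone). Cell cycle genes had a median log2 fold change of -2.60 and a list test adjusted p = 6.49e-18 (adjusted p = 0.0361 with an estimated correlation). Cdk1, the mitotic kinase, fell 12.2-fold, the topoisomerase Top2a 12.1-fold, and the kinesins Kif2c and Kif11 11.4-fold and 11.1-fold. Of 17 measured immature and repair Schwann cell genes, 3 rose and 12 fell (3 and 13 adjusted over the list alone). Immature and repair genes had a median log2 fold change of -0.94 (-0.88 with members below background at their bound) and a list test adjusted p = 0.00206 (adjusted p = 0.061 with an estimated correlation). Sox11 fell 11.7-fold, the endothelin receptor gene Ednrb 4.76-fold and Ngfr, the low-affinity neurotrophin receptor, 3.12-fold (log2 fold change -1.64 ± 0.079). Of 20 measured Schwann cell transcription factors, 4 rose and 8 fell (4 and 8 adjusted over the list alone). Those factors had a median log2 fold change of -0.16 and a list test adjusted p = 0.256. Egr2, a zinc finger factor required for myelination, had a log2 fold change of -0.038 ± 0.088 (adjusted p = 0.734), from 12.06 ± 0.10 in newborn to 12.02 ± 0.032 at P10. With no scaling between arrays its log2 fold change was -0.42 (adjusted p = 0.0144), near the median of all genes in that setting (-0.45). Over all alternatives its adjusted p ranged from 0.0144 to 0.893. Egr1 fell 8.22-fold, Egr3 4.82-fold and Etv5 4.58-fold, and Nab1, a partner of Egr proteins, rose 3.97-fold.

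Growth and matrix genes also fell. Of 11 measured imprinted growth genes, 0 rose and 10 fell (0 and 10 adjusted over the list alone). Imprinted genes, which are expressed from a single parental copy, had a median log2 fold change of -1.03 and a list test adjusted p = 0.000115 (adjusted p = 0.061 with an estimated correlation). Mest fell 13-fold, Cdkn1c 6.51-fold and Grb10 4.96-fold. Of 19 measured fibrillar collagen and matrix genes, 3 rose and 13 fell (3 and 13 adjusted over the list alone). Collagen and matrix genes had a median log2 fold change of -1.06 (-1.04 with members below background at their bound) and a list test adjusted p = 0.00163 (adjusted p = 0.061 with an estimated correlation). Tenascin C (Tnc) fell 8.32-fold and fibronectin (Fn1) 4.71-fold. Of 20 measured ribosomal protein genes, 0 rose and 17 fell (0 and 17 adjusted over the list alone). Ribosomal protein genes had a median log2 fold change of -0.59 and a list test adjusted p = 0.000462 (adjusted p = 0.061 with an estimated correlation). Rpl12 fell 2-fold. Of 23 measured oxidative phosphorylation genes, 0 rose and 8 fell (0 and 6 adjusted over the list alone). Oxidative phosphorylation genes had a median log2 fold change of -0.22 and a list test adjusted p = 0.0358 (adjusted p = 0.149 with an estimated correlation). Sdhb fell 1.61-fold. The oxidative phosphorylation call was lost without P10 replicate 1 (adjusted p = 0.0506), without P10 replicate 3 (adjusted p = 0.0501) and with 75th percentile scaling (adjusted p = 0.0836), with a range of 0.0146 to 0.149 over all alternatives. In the basal lamina list, 8 of 20 measured genes rose and 7 fell (8 and 7 adjusted over the list alone, list test adjusted p = 0.65).

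The largest single rises were in genes outside the myelin list. Fam178b gained 97.9-fold (log2 fold change 6.61 ± 0.17), Sptb, a spectrin of the membrane skeleton, 73.7-fold, Them5 at least 28.8-fold, the metallothionein gene Mt3 45.9-fold and Serpind1 at least 18.2-fold. Other probes rose less, with log2 fold changes of 2.01 and 3.12 for Sptb and 0.61 and 1.77 for Them5. H2-DMb1 and H2-DMb2 rose 47.8-fold and 44.7-fold, and complement C4a 32.4-fold. Each has a near-identical paralog, so the values of the separate copies are uncertain. The largest falls included the muscle genes Myl1 (29.1-fold), Myh8 (at least 14-fold) and Acta1 (25.5-fold). Mfap4 fell at least 19-fold, Bmp3 at least 16-fold, Igf2bp3 22.6-fold, Gldc at least 19-fold and St8sia2, a polysialic acid synthase, at least 11.9-fold.

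Antigen presentation and clock genes rose in part. Of 18 measured antigen presentation genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone). Antigen presentation genes had a median log2 fold change of 0.39 and a list test adjusted p = 0.00611 (adjusted p = 0.183 with an estimated correlation). With no scaling between arrays, where the median of all genes was -0.45, the list's median was -0.074 (adjusted p = 0.0165). H2-DMa, which helps load peptides onto class II molecules, rose 16.1-fold. Of 12 measured circadian clock genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone). Clock genes had a median log2 fold change of 0.61 and a list test adjusted p = 0.0253 (adjusted p = 0.147 with an estimated correlation). Dbp rose 4.23-fold and Per3 3.62-fold, and a dimmer Per3 probe had a log2 fold change of 0.77. Hour of collection was not among the sample variables used here, so its effect on clock genes was not tested in any comparison. Among neurotrophic genes, 2 of 14 measured members rose and 10 fell (2 and 10 adjusted over the list alone, list test adjusted p = 0.0815). Ret, a receptor of glial neurotrophic factors, rose at least 15.9-fold and Igf1 fell 4.33-fold. Among interferon-stimulated genes, 3 of 13 measured members rose and 7 fell (3 and 7 adjusted over the list alone, list test adjusted p = 0.682), and among immediate early genes, 0 of 12 measured members rose and 5 fell (0 and 5 adjusted over the list alone, list test adjusted p = 0.0557). The immediate early list had adjusted p = 0.0452 without P10 replicate 1, 0.0437 without P60 replicate 3, 0.0383 with 75th percentile scaling, 0.0402 with no scaling between arrays and 0.0453 with the replicate number as a block, with a range of 0.0383 to 0.295 over all alternatives.

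Markers of some other cell types were lower at P10, in the same step as the falls in matrix and growth genes. A link between these shifts was not tested. Of 13 measured skeletal muscle markers, 1 rose and 12 fell (1 and 12 adjusted over the list alone). Muscle markers had a median log2 fold change of -1.66 and a list test adjusted p = 2.22e-05 (adjusted p = 0.158 with an estimated correlation). Of 7 measured mast cell markers, 0 rose and 7 fell (0 and 7 adjusted over the list alone). Mast cell markers had a median log2 fold change of -2.15 (-1.47 with members below background at their bound) and a list test adjusted p = 0.00221 (adjusted p = 0.183 with an estimated correlation). Cpa3 fell at least 4.22-fold and Kit 4.7-fold. Among perineurial markers, 1 of 6 measured genes rose and 4 fell (1 and 4 adjusted over the list alone, list test adjusted p = 0.104), and Cldn1 fell 9.02-fold. Among cartilage and bone markers, 0 of 3 measured genes rose and 2 fell (0 and 2 adjusted over the list alone, list test adjusted p = 0.0676), and Col2a1 fell 14.8-fold. That list passed without newborn replicate 2 (adjusted p = 0.0486, range over all alternatives 0.0486 to 0.183). For endothelial markers, 4 of 14 measured genes rose and 6 fell (4 and 6 adjusted over the list alone, list test adjusted p = 0.704), for macrophage markers, 1 of 16 measured genes rose and 6 fell (1 and 6 adjusted over the list alone, list test adjusted p = 0.269), and for fibroblast markers, 2 of 11 measured genes rose and 6 fell (2 and 7 adjusted over the list alone, list test adjusted p = 0.173).

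From P10 to P60, genes of lipid synthesis fell back, imprinted growth genes fell further, and genes of antigen presentation and interferon response rose. Of 18 measured cholesterol synthesis genes, 1 rose and 14 fell (1 and 15 adjusted over the list alone). The cholesterol list had a median log2 fold change of -1.07 and a list test adjusted p = 3.58e-07 (adjusted p = 0.0361 with an estimated correlation). Lss fell 4.43-fold (log2 fold change -2.15 ± 0.13, -0.10 for a dimmer probe), Insig1, a brake on sterol synthesis, 3.83-fold and Mvd 3.33-fold. Of 15 measured fatty acid genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone). Fatty acid genes had a median log2 fold change of -0.32 and a list test adjusted p = 0.0194 (adjusted p = 0.149 with an estimated correlation). Acss2 fell 1.97-fold and Scd1 1.88-fold. Of 14 measured sphingolipid and galactolipid genes, 1 rose and 6 fell (1 and 9 adjusted over the list alone). Sphingolipid and galactolipid genes had a median log2 fold change of -0.27 and a list test adjusted p = 0.0242 (adjusted p = 0.269 with an estimated correlation). Ugt8a fell 1.53-fold, and the list's adjusted p was 0.0554 with no scaling between arrays (range over all alternatives 0.00492 to 0.269).

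The myelin list did not pass the list test in this step. Of 18 measured myelin protein genes, 1 rose and 7 fell (2 and 8 adjusted over the list alone). Myelin genes had a median log2 fold change of -0.093 and a list test adjusted p = 0.0945. With no scaling between arrays the median was 0.014, and the adjusted p 0.0415 for a shift down against other genes. With 75th percentile scaling it was 0.0429, with a range of 0.0415 to 0.339 over all alternatives. Pmp2, a lipid-binding myelin protein, fell 2.01-fold and S100b rose 1.82-fold. The bright probe of Mbp had a log2 fold change of 0.033 ± 0.10 (adjusted p = 0.819) and 4 dimmer probes had -1.30, -1.34, -1.79 and 0.16. Pmp22 had a log2 fold change of -0.31 ± 0.11 (adjusted p = 0.0517, 0.0395 without newborn replicate 2, range over all alternatives 0.0179 to 0.178). Egr2 had 0.024 ± 0.088 (adjusted p = 0.852) and Ngfr -0.21 ± 0.079 (adjusted p = 0.0596, 0.0466 without P60 replicate 3, range over all alternatives 0.00886 to 0.871). Among Schwann cell transcription factors, 2 of 20 measured genes rose and 5 fell (2 and 5 adjusted over the list alone, list test adjusted p = 0.568). Among immature and repair Schwann cell genes, 3 of 17 measured members rose and 7 fell (3 and 8 adjusted over the list alone, list test adjusted p = 0.322). Without P60 replicate 3 that list had adjusted p = 0.0274 (range over all alternatives 0.0274 to 0.371).

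Imprinted growth genes included some of the largest falls of this step. Of 11 measured imprinted growth genes, 1 rose and 10 fell (1 and 10 adjusted over the list alone). Imprinted genes had a median log2 fold change of -1.19 and a list test adjusted p = 4.46e-07 (adjusted p = 0.0361 with an estimated correlation). Dlk1 fell 40.4-fold (log2 fold change -5.34 ± 0.16, adjusted p = 2.61e-08). Igf2, a fetal growth factor, fell 27.6-fold, from 14.67 ± 0.059 at P10 to 9.88 ± 0.12 at P60, after 14.74 ± 0.21 in newborn. Of 33 measured cell cycle genes, 1 rose and 22 fell (2 and 23 adjusted over the list alone). The cell cycle list had a median log2 fold change of -0.80 (-0.51 with members below background at their bound) and a list test adjusted p = 7.62e-09 (adjusted p = 0.061 with an estimated correlation). Prc1, a mitotic spindle protein, fell 4.12-fold. The histone genes H2ac22, H2ac24 and H2ac7 fell 10.8-fold, 9.14-fold and 8.54-fold, with the values of these near-identical copies uncertain. Hnrnpl fell 8.63-fold (-0.77 on the log2 scale for a dimmer probe) and Ggact 8.15-fold.

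Matrix genes fell as well. Of 19 measured fibrillar collagen and matrix genes, 4 rose and 10 fell (4 and 10 adjusted over the list alone). Fibrillar collagen and matrix genes had a median log2 fold change of -0.60 and a list test adjusted p = 0.0339 (adjusted p = 0.149 with an estimated correlation). Thbs2 fell 5.69-fold and Col3a1 4.19-fold. The collagen list's adjusted p was 0.061 without P60 replicate 1 and 0.0513 without P60 replicate 2 (range over all alternatives 0.00494 to 0.149). Of 20 measured basal lamina genes, 2 rose and 14 fell (2 and 15 adjusted over the list alone). Basal lamina genes had a median log2 fold change of -0.63 and a list test adjusted p = 0.000424 (adjusted p = 0.061 with an estimated correlation). The laminin chain Lamc1 fell 2.99-fold and nidogen 2 (Nid2) 2.76-fold, while Lama5 rose 2.07-fold. Among neurotrophic genes, 2 of 14 measured members rose and 5 fell (3 and 5 adjusted over the list alone, list test adjusted p = 0.511). Among oxidative phosphorylation genes, 2 of 23 measured members rose and 0 fell (2 and 0 adjusted over the list alone, list test adjusted p = 0.936), with a median of 0.0048 and a mean of -0.0074. Among ribosomal protein genes, 0 of 20 measured members rose and 1 fell (0 and 0 adjusted over the list alone, list test adjusted p = 0.65).

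Immune and clock genes rose. Of 18 measured antigen presentation genes, 15 rose and 0 fell (15 and 0 adjusted over the list alone). The antigen presentation list had a median log2 fold change of 1.07 (1.01 with members below background at their bound) and a list test adjusted p = 1.62e-07 (adjusted p = 0.061 with an estimated correlation). Cd74, the class II invariant chain, rose 7.06-fold (log2 fold change 2.82 ± 0.13), and the class II genes H2-Eb1, H2-Ab1 and H2-Aa rose 6.33-fold, 4.64-fold and 4.62-fold. Of 13 measured interferon-stimulated genes, 12 rose and 0 fell (12 and 0 adjusted over the list alone). Interferon-stimulated genes had a median log2 fold change of 0.59 (0.58 with members below background at their bound) and a list test adjusted p = 5.47e-06 (adjusted p = 0.061 with an estimated correlation). Ifit3 rose 3.16-fold, Rsad2 2.5-fold and Irf7 at least 2.36-fold. Of 12 measured immediate early genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone). Immediate early genes had a median log2 fold change of 0.54 and a list test adjusted p = 0.0128 (adjusted p = 0.194 with an estimated correlation). Ier3 rose 2.47-fold and Junb 2.3-fold. Of 12 measured circadian clock genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone). The clock list had a median log2 fold change of 0.43 and a list test adjusted p = 0.0374 (adjusted p = 0.149 with an estimated correlation). Nr1d1, a repressor in the clock, rose 4.09-fold, while Per3 fell at least 4.09-fold (-0.54 on the log2 scale for a dimmer probe). The clock call was lost without P10 replicate 2 (adjusted p = 0.0576) and without P60 replicate 1 (adjusted p = 0.0504), with a range of 0.0213 to 0.149 over all alternatives.

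Shh, the sonic hedgehog ligand, was among the largest single rises and rose at least 14.6-fold (adjusted p = 1.66e-07, measured log2 fold change 2.12 for a dimmer probe). Cma2 rose 16.3-fold, Ppl at least 6.25-fold, Map3k21 at least 7.44-fold, Mup2 at least 5.83-fold, Mcpt4 at least 6.64-fold and Gpnmb 10.2-fold, where a dimmer Gpnmb probe had a log2 fold change of 1.54. Of 13 measured skeletal muscle markers, 9 rose and 1 fell (10 and 2 adjusted over the list alone). The muscle list had a median log2 fold change of 1.41 (1.30 with members below background at their bound) and a list test adjusted p = 5.30e-05 (adjusted p = 0.168 with an estimated correlation). Myl1 rose 12.8-fold. Of 7 measured mast cell markers, 6 rose and 1 fell (6 and 1 adjusted over the list alone). The mast cell list had a median log2 fold change of 2.63 (1.97 with members below background at their bound) and a list test adjusted p = 0.00239 (adjusted p = 0.183 with an estimated correlation). Of 6 measured perineurial markers, 5 rose and 0 fell (5 and 0 adjusted over the list alone). Perineurial markers had a median log2 fold change of 1.18 and a list test adjusted p = 0.000462 (adjusted p = 0.0773 with an estimated correlation). Of 4 measured neuron markers, out of 17 listed, 3 rose and 0 fell (3 and 0 adjusted over the list alone). Neuron markers had a median log2 fold change of 1.07 and a list test adjusted p = 0.0196 (adjusted p = 0.158 with an estimated correlation). Uchl1 rose 2.37-fold and Stmn2 2.23-fold. Of 3 measured erythroid markers, out of 14 listed, 0 rose and 2 fell (0 and 3 adjusted over the list alone). Erythroid markers had a median log2 fold change of -0.84 and a list test adjusted p = 0.0323 (adjusted p = 0.155 with an estimated correlation). Without P60 replicate 2 the erythroid list had adjusted p = 0.0526 (range over all alternatives 0.00716 to 0.155). These cell markers changed in the same step as the immune genes above, and a link was not tested. Among macrophage markers, 3 of 16 measured genes rose and 1 fell (2 and 1 adjusted over the list alone, list test adjusted p = 0.831), and Cx3cr1 fell 3.61-fold while Lyz2 rose 2.59-fold. For endothelial markers, 5 of 14 measured genes rose and 1 fell (5 and 1 adjusted over the list alone, list test adjusted p = 0.0742), with adjusted p = 0.033 without P60 replicate 3, 0.0429 with 75th percentile scaling, 0.0415 with no scaling between arrays and a range of 0.033 to 0.318 over all alternatives. With array weights, 6160 genes changed in this step against 3955 without them.

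**Figure D2:**
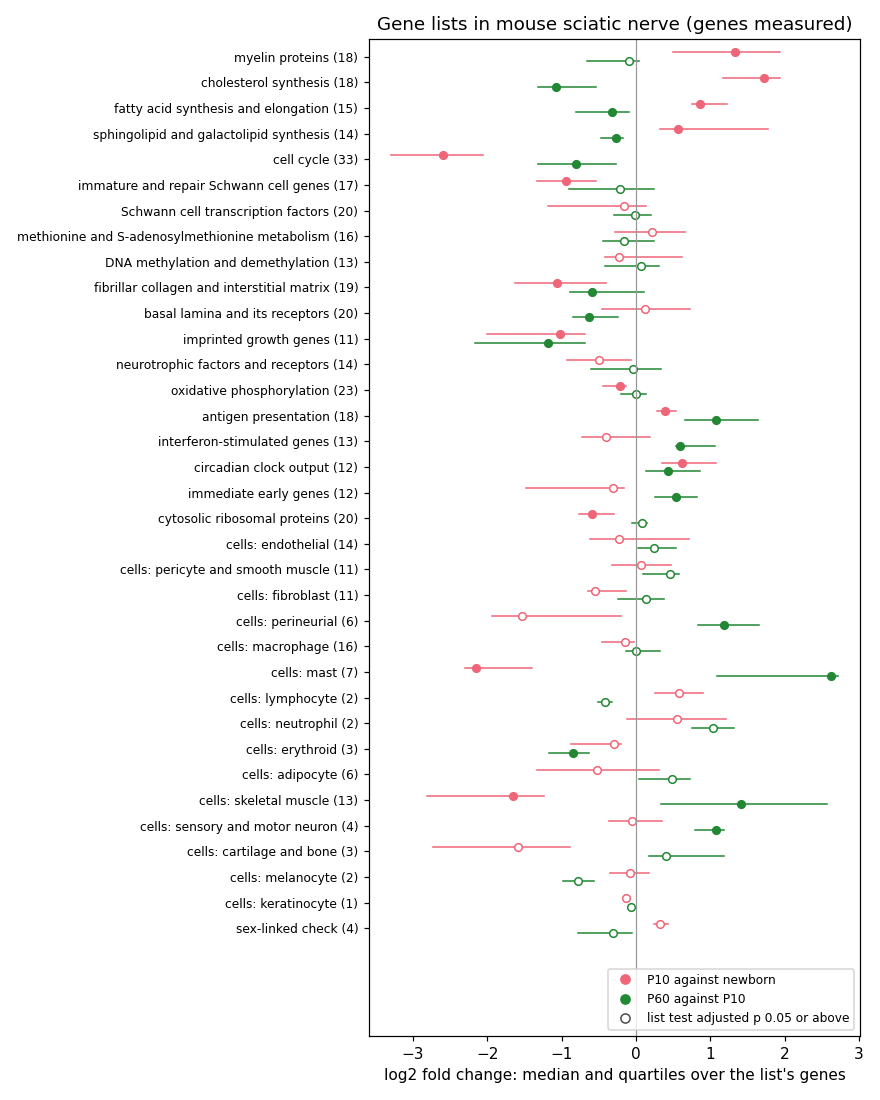
Median log2 fold change (dots) and quartiles (lines) over the measured genes of each list, for P10 against newborn and P60 against P10, with 3 arrays per stage and the number of genes in brackets. Filled dots passed the list test with the preset correlation, as cholesterol synthesis did with medians of 1.73 and then -1.07.

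Lists for the methyl cycle and for DNA methylation did not pass the list test in either step, while single members changed. In the methionine and S-adenosylmethionine list, 7 of 16 measured genes rose and 5 fell (7 and 5 adjusted over the list alone, list test adjusted p = 0.616) by P10. From P10 to P60, 2 of 16 measured genes rose and 6 fell (3 and 6 adjusted over the list alone, list test adjusted p = 0.368). Shmt1 fell 3.69-fold and Mthfd1 rose 2.41-fold by P10, and Ahcy, which clears S-adenosylhomocysteine, fell 2.17-fold from P10 to P60. Gnmt lay near the detection limit, detected on 2 newborn, 2 P10 and 0 P60 arrays. Its measured log2 fold change was 0.18 ± 0.18 by P10 (adjusted p = 0.436) and -0.63 ± 0.18 afterwards (adjusted p = 0.0223), a fall of at least 1.12-fold. The second call was lost without P10 replicate 2 (adjusted p = 0.0774), P10 replicate 3 (adjusted p = 0.0722) or P60 replicate 2 (adjusted p = 0.0706), and with no scaling between arrays (adjusted p = 0.0536), with a range of 0.00951 to 0.0774 over all alternatives.

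In the DNA methylation and demethylation list, 4 of 13 measured genes rose and 6 fell (4 and 6 adjusted over the list alone, list test adjusted p = 0.65) by P10. From P10 to P60, 4 of 13 measured genes rose and 4 fell (4 and 4 adjusted over the list alone, list test adjusted p = 0.657), with a median log2 fold change of 0.064, a mean of -0.17 and a test that pointed down. Dnmt1, the maintenance methyltransferase, fell 2.5-fold by P10 (log2 fold change -1.32 ± 0.29). It then had -0.40 ± 0.29 (adjusted p = 0.308), and 0.033 without P60 replicate 3. Uhrf1, which brings Dnmt1 to DNA, fell 8.65-fold and then 4.38-fold. Tet1 fell 2.15-fold in the second step, and the damage-response gene Gadd45b rose 1.87-fold and then 2.3-fold. Dnmt3b had log2 fold changes of -0.26 ± 0.14 by P10 (adjusted p = 0.147, 0.00528 without P60 replicate 3, range over all alternatives 0.000209 to 0.289) and -0.20 ± 0.14 afterwards (adjusted p = 0.304). The fall by P10 also passed with array weights (adjusted p = 0.0121), only the 6 arrays compared (adjusted p = 0.0092) and no scaling between arrays (adjusted p = 0.000209). In the other alternatives Dnmt3b did not pass by P10. From newborn to P60 it fell 1.37-fold (log2 fold change -0.46 ± 0.14, adjusted p = 0.0167), and the call was lost without newborn replicate 2 (adjusted p = 0.0527, range over all alternatives 0.000163 to 0.0527). Over that interval its log2 fold change was -0.27 without P60 replicate 3 and -0.77 with no scaling between arrays. Mki67, Dnmt3a and Mat2a were not analysed here.

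Over the whole interval from newborn to P60, C4a and Sptb were among the genes that rose most and H2ac22 and H2ac12 among those that fell most. In all, 3487 genes rose and 3455 fell, 1365 and 1267 of them by 2-fold or more, against 2061 and 4865 in all with no scaling between arrays. C4a rose 158-fold (log2 fold change 7.30 ± 0.13), Sptb 140.3-fold, Them5 at least 72.8-fold, Fam178b 95.4-fold, Serpind1 at least 46-fold, Mt3 69.2-fold and the acute phase gene Serpina3n 66.6-fold. Dimmer probes had log2 fold changes of 3.00 and 0.17 for Sptb and 1.20 and 3.25 for Them5. C4b rose 81-fold, with log2 fold changes of 1.48 and 1.67 for its dimmer probes. H2ac22 fell 122-fold, H2ac12 at least 50.3-fold, H2ac24 65.2-fold, H2ac7 64-fold and H2ac15 at least 38.5-fold. Histone copies, and the pair C4a and C4b, are near-identical and their separate values are uncertain. Dlk1 fell 110.4-fold, Ecrg4 at least 57.8-fold and Igf2bp3 at least 31.7-fold, where 1 dimmer Igf2bp3 probe had a log2 fold change of 0.36.

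Cell division and imprinted growth genes fell and myelin genes rose over the interval. Of 33 measured cell cycle genes, 0 rose and 33 fell (0 and 33 adjusted over the list alone). Cell division genes had a median log2 fold change of -3.52 (-3.28 with members below background at their bound) and a list test adjusted p = 3.08e-17 (adjusted p = 0.0361 with an estimated correlation). Of 11 measured imprinted growth genes, 0 rose and 11 fell (0 and 11 adjusted over the list alone). The imprinted list had a median log2 fold change of -3.08 and a list test adjusted p = 7.46e-07 (adjusted p = 0.0361 with an estimated correlation). Of 18 measured myelin protein genes, 15 rose and 2 fell (15 and 2 adjusted over the list alone). Myelin protein genes had a median log2 fold change of 0.72 and a list test adjusted p = 0.00161 (adjusted p = 0.149 with an estimated correlation). Drp2 rose 25.6-fold, and Pmp22 had a log2 fold change of 0.46 ± 0.11 (adjusted p = 0.00427, 0.701 with no scaling between arrays, range over all alternatives 0.000224 to 0.701). The bright probe of Mbp had 0.27 ± 0.10 (adjusted p = 0.0316) and the dimmer ones 1.28, 0.89, 0.031 and 0.45. The bright probe's adjusted p was 0.0824 without newborn replicate 1, 0.107 without newborn replicate 2, 0.0525 without P10 replicate 1, 0.0513 without P10 replicate 2 and 0.0554 without P60 replicate 3, in a range of 0.0143 to 0.516 over all alternatives. In the fit of only the 6 arrays compared it was 0.0712. Of 17 measured immature and repair genes, 2 rose and 13 fell (2 and 13 adjusted over the list alone). Immature and repair Schwann cell genes had a median log2 fold change of -1.18 (-1.16 with members below background at their bound) and a list test adjusted p = 0.00371 (adjusted p = 0.066 with an estimated correlation). Ednrb fell 17.3-fold and Shh rose at least 17.3-fold.

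Lipid, immune and clock genes rose over the same interval, and matrix and ribosomal protein genes fell. Of 18 measured cholesterol synthesis genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone). Sterol synthesis genes had a median log2 fold change of 0.46 and a list test adjusted p = 0.0236 (adjusted p = 0.149 with an estimated correlation). Sc5d rose 6.69-fold and Hsd17b7 3.54-fold. Of 15 measured fatty acid genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone). The fatty acid list had a median log2 fold change of 0.76 and a list test adjusted p = 0.0323 (adjusted p = 0.158 with an estimated correlation). Of 14 measured sphingolipid and galactolipid genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone). The sphingolipid list had a median log2 fold change of 0.64 and a list test adjusted p = 0.0339 (adjusted p = 0.293 with an estimated correlation). That list had adjusted p = 0.0661, 0.0523 and 0.0681 without P60 replicates 1, 2 and 3 in turn (range over all alternatives 0.0189 to 0.293). Of 19 measured collagen and matrix genes, 4 rose and 15 fell (4 and 15 adjusted over the list alone). The collagen list had a median log2 fold change of -1.67 (-1.62 with members below background at their bound) and a list test adjusted p = 0.000692 (adjusted p = 0.061 with an estimated correlation). Col3a1 fell 12-fold and Thbs2 16.1-fold.

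Of 20 measured ribosomal protein genes, 0 rose and 15 fell (1 and 15 adjusted over the list alone). The ribosomal list had a median log2 fold change of -0.57 and a list test adjusted p = 0.00311 (adjusted p = 0.061 with an estimated correlation). Of 18 measured antigen presentation genes, 17 rose and 0 fell (17 and 0 adjusted over the list alone). Genes of antigen presentation had a median log2 fold change of 1.71 and a list test adjusted p = 3.86e-07 (adjusted p = 0.061 with an estimated correlation). Cd74 rose 10.6-fold and H2-DMa 17.6-fold. Of 13 measured interferon-stimulated genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone). The interferon list had a median log2 fold change of 0.46 and a list test adjusted p = 0.0323 (adjusted p = 0.186 with an estimated correlation). Without newborn replicate 3 the interferon list had adjusted p = 0.0642 (range over all alternatives 0.0178 to 0.186). Of 12 measured circadian clock genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone). Circadian clock genes had a median log2 fold change of 1.20 and a list test adjusted p = 0.0222 (adjusted p = 0.139 with an estimated correlation). Dbp rose 6.3-fold and Nr1d1 5.6-fold. Among immediate early genes, 5 of 12 measured members rose and 5 fell (5 and 5 adjusted over the list alone, list test adjusted p = 0.838), with a median of 0.13 and a mean of -0.29.

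**Figure D3:**
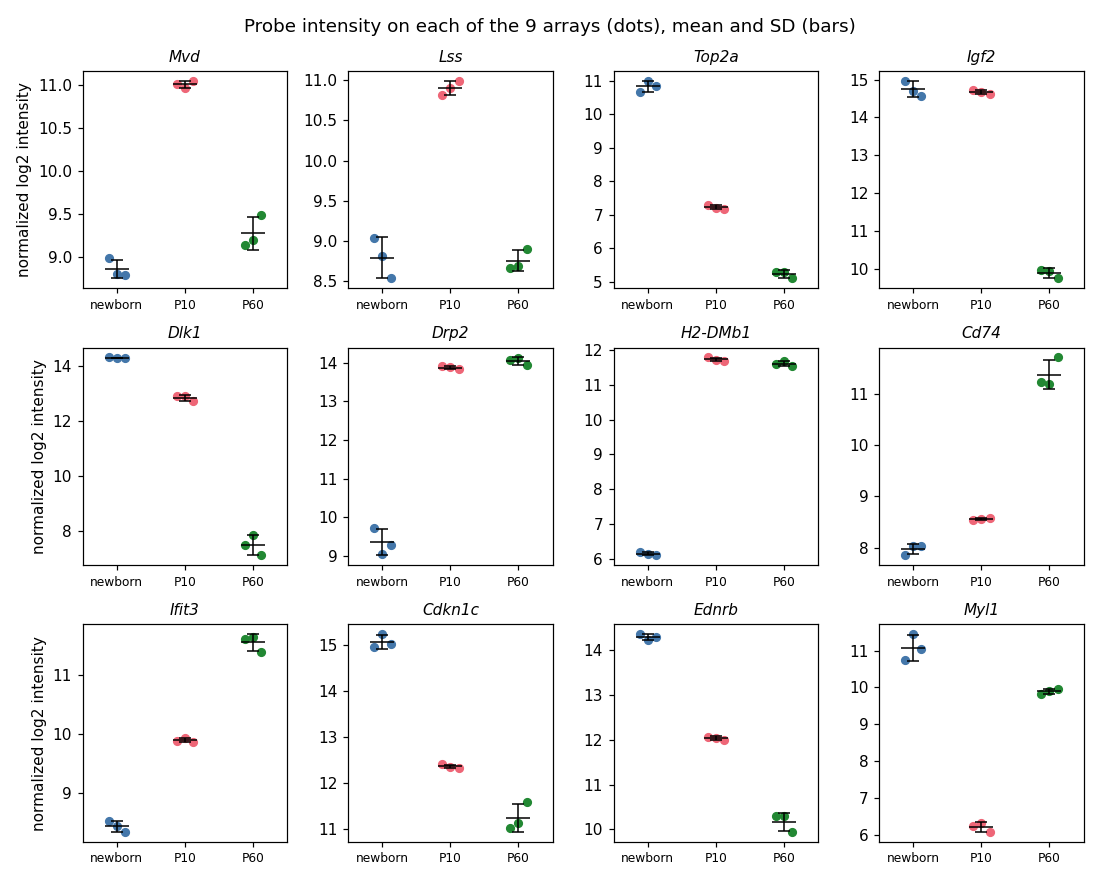
Normalized log2 intensity of 12 genes on each of the 9 arrays (dots, coloured by stage), with the mean and SD of 3 arrays (bars) and a separate y axis per gene. Igf2 lies at 14.74, 14.67 and 9.88 in newborn, P10 and P60, and Lss at 8.80, 10.90 and 8.76.

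For many genes P10 did not lie between the other stages. Genes that peaked at P10 included the glycolytic gene Aldoc, with a contrast of P10 against the mean of the other stages of 2.70 ± 0.080 on the log2 scale, and Fam107a (2.50 ± 0.11). Peaks with another stage below background on every array have only a bound, a contrast of at least 2.80 for Ret, 2.38 for Cdh3, 2.05 for Mobp and 1.94 for Per3. Genes with a trough included Myl1 (-4.27 ± 0.14) and Col2a1 (-2.93 ± 0.16), and Acta1 (-3.68 ± 0.19) and Cma2 (-2.92 ± 0.18), each detected on 1 P10 array. No P10 array detected Bmp3 or Tnnc2, whose contrasts were -2.68 or lower and -2.05 or lower. This contrast passed the threshold for 4475 genes, 2131 above and 2344 below, or 840 above and 4904 below with no scaling between arrays. It also passes where P10 lies between the other stages but the 2 steps differ in size. Actn2, at 7.35, 6.12 and 5.79 in stage order, passed with -0.45 ± 0.096. The count is therefore not one of peaks and troughs. A peak, with a rise and then a fall, was called for 586 genes and a trough for 546. Another 851 genes rose in both steps and 747 fell in both. With no scaling between arrays the peaks were 188, the troughs 1159 and the genes rising in both steps 529, and without P60 replicate 3 the troughs were 866.

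Both steps share the P10 arrays, whose chance values move the steps in opposite directions (correlation across unchanged genes -0.502 in simulations). They can therefore add to peaks and troughs and not to rises or falls in both steps. Part of any excess of peaks may come from them, since 3 arrays cannot be split into groups of 2. In 20 simulations with every gene unchanged, where adjusted calls are rare, each pattern held 0 genes, which does not bear on genes that do change. Independent lists of the same lengths would share 569 genes for peaks, 619.8 for troughs, 608 for rises and 581 for falls. Across genes, the covariance of the log2 fold changes of the 2 steps was 0.0653, against -0.00998 in the simulations, a difference of 0.0753.

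The remaining marker lists did not pass the list test by P10. For pericyte and smooth muscle markers, 3 of 11 measured genes rose and 3 fell (3 and 3 adjusted over the list alone, list test adjusted p = 0.753) by P10. For adipocyte markers, 1 of 6 measured genes rose and 3 fell (1 and 3 adjusted over the list alone, list test adjusted p = 0.616) by P10. In the lymphocyte list, 1 of 2 measured genes rose and 0 fell (1 and 0 adjusted over the list alone, list test adjusted p = 0.394), and in the neutrophil list, 1 of 2 measured genes rose and 1 fell (1 and 1 adjusted over the list alone, list test adjusted p = 0.77), over the same interval. In the melanocyte list, 1 of 2 measured genes rose and 1 fell (1 and 1 adjusted over the list alone, list test adjusted p = 0.856), and in the keratinocyte list, 0 of 1 measured genes rose and 0 fell (0 and 0 adjusted over the list alone, list test adjusted p = 0.817). Among neuron markers, 1 of 4 measured genes rose and 1 fell (1 and 1 adjusted over the list alone, list test adjusted p = 0.947) by P10, with a median of -0.060 and a mean of 0.044. From P10 to P60, 3 of 11 measured fibroblast markers rose and 3 fell (5 and 3 adjusted over the list alone, list test adjusted p = 0.616). In the same step, 0 of 2 measured melanocyte markers rose and 2 fell (0 and 2 adjusted over the list alone, list test adjusted p = 0.0676). The melanocyte list had adjusted p = 0.0319 with no background correction, 0.0425 with the authors' log2 table and 0.0415 with no scaling between arrays (range over all alternatives 0.0319 to 0.249).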

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

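No scaling between arrays and the replicate block over the P10 and P60 arrays alone were chosen after seeing the data, and the others were planned. Counts of genes or lists stayed within 1.5 times their value in 204 of the alternatives' values and left that range in 33. List tests kept their side of the threshold in 1598 values, were lost in 50 and gained in 67. Named genes kept direction and side in 8028, lost the call in 198, gained it in 19 and turned sign in 29. Signals near background limit the dim genes: in 636, 378 and 772 of the genes changed for P10 against newborn, P60 against P10 and P60 against newborn, the dimmer stage was below background on every array. The beadchip as a block was not run, since the files name no chips.

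Counts are given in the order P10 against newborn, P60 against P10, P60 against newborn, P10 against the mean of the other stages, any stage, peaks, troughs, rises in both steps and falls in both steps. All probes tested separately, with more features tested, gave 10876, 6995, 12216, 7954, 13663, 1212, 900, 1327 and 1200. A minimum log2 fold change of 1, a stricter call by construction, gave 1913, 796, 2632, 589, 3099, 78, 53, 95 and 117. Array weights moved P60 against P10 to 6160, peaks to 1005, troughs to 1044, rises to 1381 and falls to 1179, and the cause was not tested. Spread differed by stage: the SD of deviations from the stage mean was 0.29 for P60 replicate 3, 0.161 and 0.182 for the other P60 arrays and 0.0949 to 0.106 at P10. A shared spread can then be too large for P10 against newborn and too small where P60 is compared. Fits of only the 6 arrays compared gave 7338, 3316 and 6409 genes, against 6202, 3955 and 6942. No scaling between arrays shifted the median of all genes by -0.45, 0.15 and -0.32 in the 3 stage comparisons. It gave 188 peaks, 1159 troughs and 529 rises in both steps. Lists called numbered 2, 2 and 2 with an estimated correlation and 28, 29 and 28 by fry, which does not compare a list with other genes, against 14, 16 and 12.

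Leaving out each array in turn gave 5222 to 7366 genes for P10 against newborn, 3053 to 4891 for P60 against P10, 6029 to 7505 for P60 against newborn, 3321 to 5843 for P10 against the mean of the others and 6657 to 8512 for any stage. Peaks ranged from 411 to 809, troughs from 390 to 866, rises in both steps from 640 to 1122 and falls in both from 553 to 942. Lists called ranged from 13 to 15, 14 to 18 and 11 to 13. The highest gene count of each came without P60 replicate 3.

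These values turned sign, and of them Pmel, Uty, Mbp (P60 against newborn) and Gsn were called with all arrays and neqc. With 75th percentile scaling Egr2 had 0.049 for P10 against newborn and 0.10 for P60 against newborn, and Mbp -0.12 for P60 against P10. With array weights Mbp had -0.024 and Dnmt1 0.0020 (against -0.40) for P60 against P10, and Egr2 0.035 for P60 against newborn. With no scaling between arrays, Pmel had -0.015, Uty -0.068, Mbp -0.10 and Gnmt -0.20 for P10 against newborn, Mbp -0.0039 for P60 against P10, and Uty -0.11 and Mbp -0.10 for P60 against newborn. Egr2 had 0.018 (P10 against newborn) and 0.041 (P60 against newborn) without newborn replicate 3, -0.012 (P60 against P10) without P60 replicate 1, and 0.043 (P60 against newborn) without P60 replicate 3. Without P60 replicate 3, Mbp had -0.030 and Dnmt1 0.033 for P60 against P10. Gsn has probes that oppose each other, and in these settings another probe became the brightest. For P60 against P10 and P60 against newborn it had 1.86 and 1.82 without newborn replicate 1, 1.86 and 2.06 without newborn replicate 2, 1.85 and 1.80 without newborn replicate 3, 1.81 and 1.92 without P10 replicate 2, 1.78 and 1.93 without P10 replicate 3, against -0.62 and -0.76 with all arrays. Apart from Gsn, the cause was not tested. Leaving out each array in turn gave -0.62 to 0.033 for Dnmt1 (P60 against P10), -0.070 to 0.018 for Egr2 (P10 against newborn), -0.012 to 0.082 for Egr2 (P60 against P10), -0.050 to 0.043 for Egr2 (P60 against newborn), 0.029 to 0.34 for Gnmt (P10 against newborn), -0.82 to 1.86 for Gsn (P60 against P10), -0.96 to 2.06 for Gsn (P60 against newborn), 0.19 to 0.33 for Mbp (P10 against newborn), -0.030 to 0.072 for Mbp (P60 against P10), 0.20 to 0.37 for Mbp (P60 against newborn), 0.33 to 0.56 for Pmel (P10 against newborn), 0.25 to 0.37 for Uty (P10 against newborn), 0.20 to 0.27 for Uty (P60 against newborn).

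With the replicate number as a block, 6136, 3846 and 6893 genes changed in the 3 stage comparisons. The immediate early list for P10 against newborn (adjusted p = 0.0453) and the erythroid list for P60 against newborn (adjusted p = 0.0481) became called under the block, and S100a8 and Alpl (P60 against P10) and Uty (P60 against newborn) lost their call. No other list or named gene changed its call in that fit. With the block over the P10 and P60 arrays alone, 3293 genes changed from P10 to P60, against 3316 in those 6 arrays without it. Ndufs7, Rpl10a, Alpl and Dct lost their call there, and no list changed its call. Pairing of the P10 and P60 arrays was not settled, and newborn arrays were not taken as paired with the others.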

Other observations

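The tests of cell mix, batch, sex, dilution, adhering muscle and macrophages were chosen only after the result was seen, as were the class II contrasts. The choice of Kit, Slc2a1, Tjp1, Myh8, Actn2 and Tnnt1 as exceptions was also made then. Genes of class II antigen presentation followed different courses. The contrast of P10 against the mean of the other stages was 1.94 ± 0.081 for H2-DMa and 2.85 ± 0.068 for H2-DMb1, whose products load peptides. It was -0.92 ± 0.12 for H2-Aa (detected on 1 newborn and 1 P10 array), -0.94 ± 0.077 for H2-Ab1, -1.06 ± 0.12 for H2-Eb1 and -1.12 ± 0.12 for Cd74, the class II chains and their chaperone. All 6 had an adjusted p of 0.000229 or lower. H2-DMb1 has a near-identical paralog, so its share of that value is uncertain.

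Xist, the RNA that silences an X chromosome in females, fell 2.71-fold from P10 to P60 (log2 fold change -1.44 ± 0.16, adjusted p = 8.53e-05, dimmer probes -1.46, -0.78 and -0.16). Its level was 10.21 ± 0.19 in newborn, 10.28 ± 0.029 at P10 and 8.84 ± 0.34 at P60. Of 4 measured sex-linked genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone). This list had a median log2 fold change of -0.31 and a list test adjusted p = 0.248. It pools Xist with Y-linked genes, which a different mix of sexes would move in opposite directions. The median and list test therefore cannot address whether that mix differed by stage. Among endothelial genes, the tight junction gene Cldn5 rose 3.04-fold by P10 and 1.91-fold afterwards, while Plvap, a protein of fenestrated vessels, fell 2.37-fold by P10. The elastic fibre gene Mfap5 rose 2.51-fold and then 3.58-fold.

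P60 replicate 3 differed from its stage mean by over 0.5 on the log2 scale for 914 genes, against 51 and 116 for the other P60 arrays. Markers of all other cell types, pooled, deviated 0.872 ± 0.125 times as much as all genes (median absolute deviation, bootstrap SD over genes of this array). No excess was seen in the pooled markers. A change in a few cell types, or in the share of Schwann cells, could leave this ratio low, so a different cell mix stays open. The deviations of P60 replicate 3 went with those of newborn replicate 2 and P10 replicate 3, with a lowest pairwise correlation across genes of 0.112. A shared batch stays open, since the labels name none. The signal column of newborn replicate 2 alone carries the suffix rep, whose meaning is not given. Fewer males in this pool would lower Y-linked genes, and Eif2s3y was at 6.94 against 8.43 and 8.46, Kdm5d at 5.41 against 5.78 and 5.76 and Uty at 5.48 against 5.58 and 5.62, but it would also raise Xist, which was lower than on both (-0.451 from their mean, with 0.442 between them), so this stays open. Newborn replicate 2 also had lower Eif2s3y (7.18 against 8.15 and 8.27) and Kdm5d (4.91 against 5.62 and 5.50) than the other newborn arrays. Its Uty (5.30 against 5.32 and 5.37) and Xist (10.33 against 10.32 and 9.99) differed little, and P10 replicate 3 had no such drop. Sex and batch thus cannot be told apart for P60 replicate 3 and newborn replicate 2. The design names no biological difference for P60 replicate 3, and none but cell mix and sex was tested.

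Markers of muscle, mast and perineurial cells had a median contrast of P10 against the mean of the other stages of -1.91 (-1.70 with stages below background at their bound), though the perineurial Slc2a1 (-0.079 ± 0.073, adjusted p = 0.412) and Tjp1 (-0.15 ± 0.20, adjusted p = 0.584) did not pass, and Kit fell further from P10 to P60 (log2 fold change -0.55 ± 0.11, adjusted p = 0.00295). Dilution of all other cells by Schwann cell RNA would lower endothelial and macrophage markers alike, and their median contrast was -0.186 (SD 0.411; -0.18 with bounds), which argues against it. Adhering muscle in the newborn and P60 dissections stays open. Of 13 muscle genes, 12 were below that mean, among them the abundant Myl1 (at 11.08 ± 0.35, 6.22 ± 0.13 and 9.90 ± 0.064 in stage order). The other 1, Actn3, was above it, and Des is also in the pericyte list. Yet Myh8 (4.61 at P10 and 4.53 at P60), Actn2 (6.12 and 5.79) and Tnnt1 (5.76 and 5.38) were not lowest at P10. They were below the mean through the newborn level alone, and whether muscle at P60 would raise them was not tested. From P10 to P60, 9 of the 13 rose and 1 fell. Stage itself stays open, as an untested biological difference.

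Antigen presentation and interferon-stimulated genes rose from P10 to P60, with a median log2 fold change of 0.99 over both lists. The macrophage list had a median of 0.00188 (SD 0.699), below that value by more than this SD, which argues against more macrophages at P60 as the whole cause. Its members went both ways, with Lyz2 and Cd14 rising 2.59-fold and 1.57-fold and Cx3cr1 falling 3.61-fold. A change in the state of resident cells with age was not tested and stays open.

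Other splits of the samples were counted for each gene count. For 3 arrays against 3, the 10 splits are too few for a share under 0.05. In fits of those 6 arrays the real split called 7338 genes for P10 against newborn, 3316 for P60 against P10 and 6409 for P60 against newborn, and the highest other split, with those that also part the same-numbered P10 and P60 arrays, called 0, 0 and 0, so that 1 split of each gave as many. Of 100 splits of the 9 arrays, with the real one counted, 1 reached the 7678 genes of any stage (highest other 5096). Likewise 1 reached the 851 rising in both steps and 1 the 747 falling in both (highest other 0 for each). In each case that 1 was the real split, which argues against a random grouping of these arrays for these counts. Chance differences between animals or dissections are not addressed, since the replicates of a stage may be technical. For P10 against the mean of the others, 2 splits reached the 4475 genes (highest other 5722), with the real one counted. For peaks 2 splits reached 586 (highest other 2231) and for troughs 2 reached 546 (highest other 2153), counted likewise. Such splits ask whether stage matters at all, not whether peaks or troughs exceed what 2 separate steps would give. Independent lists of the same lengths would share 569 and 619.8 genes, so peaks were about as many and troughs fewer. For the contrast, peaks and troughs no conclusion is drawn from these shares. The highest other counts for any stage, this contrast, peaks and troughs all came from 1 drawn split, which set the 3 newborn arrays together in place of P10 and mixed P10 and P60 arrays in the other places, so its several times as many peaks and troughs point to the difference between newborn and later arrays.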
